A study of Mus musculus with 4 samples.

How the data were processed

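Total RNA from 4 primary mouse tumours was measured on 1-colour Affymetrix arrays, 1 array per tumour, per the labels. All 4 carry the same genotype label (mutant Alk, the TH-MYCN transgene and no functional Stat6) on a mixed C57BL/6 and 129Sv/J background, so they form 1 group. TH-MYCN mice express MYCN in cells that make tyrosine hydroxylase and develop neuroblastoma, a tumour of the sympathetic nervous system. RNA was extracted with Trizol and labelled with biotin after cDNA synthesis, per the labels' protocols. The submitters' processing notes name RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a probe set on a log scale, and Partek, an analysis package. Neither versions nor settings are given in the sources used here. The labels give the tissue as a neck muscle and the material as a primary tumour. Nothing says how the tumour was dissected.

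The deposited table holds 1 value per probe set and tumour, 41345 probe sets in all, and was used as the authors normalized it. The log base is not stated. The deposited values run from 2.47 to 13.6, as RMA values on a log2 scale do, and they are treated as log2 values here. They are not centred per gene, and scanner files, against which the scale could be set, were not used here. The array medians were 5.15, 5.19, 5.25 and 5.29 in tumours 1 to 4. No pair of arrays shared more than 0.22% of its values exactly, so each array was counted as a sample of its own. The tumours are numbered in the order of their records and the numbers carry no pairing. That the tumours came from separate animals is not stated.

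Genes were named from the platform annotation. Of the probe sets, 25335 were listed there, 23521 with 1 gene and 1814 with several, and 16010 were not listed. Only those with 1 gene were used. Symbols were updated through Entrez identifiers with the RefSeq gene table of GRCm38.p6, which matched 23328 and left 193 under their array symbol. For genes with several probe sets, of which there were 1082, the one with the highest mean was taken. This gave 22180 genes. The build behind the probe sets is not given in the sources used here, so no coordinates are printed. Apart from updating symbols and matching list members, the RefSeq table was used only to place genes on chromosomes and in order along them.

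No detection calls were used. The background was set instead by 1394 olfactory and vomeronasal receptor genes, which a tumour should not express: a gene counted as detected when its mean over the 4 tumours exceeded the 95th percentile of the receptor genes' means, a log2 value of 6.17. The receptor median was 4.01. The floor is strict, since receptor genes cross-hybridise, and a gene under it is undetermined and not shown to be absent. Levels of different probe sets depend on their probes and are not set against each other. A gene was called variable when its range over the 4 tumours was at least 1 log2 unit (2-fold).

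With 1 group there is no contrast between conditions and no p-value is given. Per gene, the mean and SD over the 4 tumours describe the level. The 31 gene lists (cell types, pathways, tumour programmes and controls) and the rule for named genes were fixed before the data were examined. For each list with at least 3 detected members, the deviation of every member from its own 4-tumour mean was taken, and the median over members was set against 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list was said to stand apart in a tumour below the 0.5th or above the 99.5th percentile. Genes of one cell type are co-expressed and genes are not replicates, so a percentile describes these arrays and tests no condition. The shifts printed are relative, with the median of all detected genes in the same bin subtracted. This form was adopted after it was seen that detected genes as a whole were offset between arrays, with median deviations of 0.12, 0.04, -0.09 and -0.08 in tumours 1 to 4; the percentiles are those of the median deviation fixed before. Receptor genes went the other way, with medians of 3.85, 3.95, 4.10 and 4.10 in tumours 1 to 4. The SD over members is given as their error. The spread of a list is the SD over the 4 tumours of its members' mean deviation, compared with random lists in the same way. Dixon's ratio, the gap of an extreme tumour to its nearest neighbour over the range, was compared with its 95% critical value of 0.829 for 4 samples, which 5.04% of simulated groups of normal values passed.

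Named genes were Stat6, Alk and Mycn, up to 3 detected members per list with the widest and up to 2 with the narrowest range, the 15 detected genes with the widest range other than immunoglobulin and T cell receptor segments, predicted genes and small RNAs, and up to 5 genes per tumour with a Dixon ratio past the critical value. Genes named outside this rule are said to be so.

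The list procedure was tested on simulated arrays with the real genes' means and SDs, 8998 genes in the step, for the shift of a list per tumour. Of the lists of 13 members lowered by 0.4 in 1 tumour, 100% were called lower, and of those lowered by 0.2, 52.5%. Of 240 unchanged lists, 0.833% were called either way. Genes were simulated independently of each other, without offsets between arrays, so a rate near that of the percentile limits follows from the setup. These rates do not carry over to lists of co-expressed genes or of other sizes. With 4 arrays the number of tumours limits the precision.

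Alternatives were median centring, a further quantile normalization, floors at the 99th percentile and the median of the receptor genes and no floor, the mean of a gene's probe sets, other thresholds of range, unmatched random lists, means in place of medians and each tumour left out in turn. Leaving out genes on X and Y, or on chromosome 3, was added after seeing the data, as was the chromosome comparison. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.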

Results

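The series addresses how Stat6, the transcription factor that carries the IL-4 and IL-13 signal and drives alternative macrophage polarization, bears on neuroblastoma growing in its own host. Gene expression was measured in 4 primary tumours from 1 group, all with mutant Alk, the TH-MYCN transgene and a Stat6-null genotype. Tumours with intact Stat6 were not analysed here, so the data give the expression profile of Stat6-deficient tumours and the spread between them. Each array held 41345 probe sets, which named 22180 genes, and 8989 of these (40.5%) lay above the background floor.

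Stat6 measured 5.83 ± 0.07 (SD, n = 4, log2 units), with the tumours between 5.75 and 5.92, and was below the floor of 6.17. Which part of the gene its probe set covers, and which part was deleted, are not given in the sources used here, so this value does not check the genotype. Alk, the receptor tyrosine kinase that the model mutates, measured 8.04 ± 0.30 (SD, n = 4), from 7.73 in tumour 2 to 8.43 in tumour 1. Mouse Mycn measured 6.49 ± 0.37 (SD, n = 4), from 6.01 in tumour 2 to 6.89 in tumour 4. The TH-MYCN transgene carries the human gene, and whether the mouse probe set also reads it is unknown. Of the measured members of the JAK-STAT6 list, 7 of 17 were detected. Il4ra, the receptor chain shared by IL-4 and IL-13, stood at 6.56 ± 0.16, Irs2, an adaptor of that receptor, at 7.45 ± 0.24 and Stat5b at 6.86 ± 0.04 (SD, n = 4). This list did not stand apart in any tumour.

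Genes of the sympathoadrenal programme were detected in full. All 27 measured members of the sympathoadrenal neuroblastoma list had a 4-tumour mean above the floor, and 26 of them also passed the floor at the 99th percentile of receptor genes. Some were nearly constant across tumours. Gata3, a transcription factor of the sympathetic lineage, measured 8.05 ± 0.04 and Cntfr, a neurotrophic cytokine receptor, 9.01 ± 0.03 (SD, n = 4). Others varied more than 2-fold: Prph, a neuronal intermediate filament, ran from 7.51 in tumour 4 to 9.32 in tumour 1, Slc6a2, the noradrenaline transporter, from 7.01 in tumour 3 to 8.22 in tumour 1, and Slc18a1, a vesicular monoamine transporter, from 6.01 in tumour 3 to 7.08 in tumour 1. Of the adrenal chromaffin list, 8 of 11 members were detected. The mesenchymal neuroblastoma list had 3 of 18 detected, Fosl2 (6.81 ± 0.37), Yap1 (6.29 ± 0.20) and Vim (11.07 ± 0.14, SD, n = 4).

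Growth programmes were detected in full. All 19 measured members of the MYC target and ribosome biogenesis list, all 19 of the cell cycle list and all 13 of the oxidative phosphorylation list lay above the floor. Npm1, a nucleolar chaperone, measured 11.12 ± 0.06, Srm, spermidine synthase, 10.63 ± 0.42, and Plk1, a mitotic kinase, 9.83 ± 0.47 (SD, n = 4). Of the ALK and MYCN axis, 11 of 19 members were detected. Among them Etv5, a transcription factor induced by ERK signalling, measured 8.19 ± 0.09 and Spry2, a feedback inhibitor of that pathway, 6.56 ± 0.04, while Dusp6, an ERK phosphatase, ranged from 6.88 in tumour 2 to 8.06 in tumour 3. The hypoxia and glycolysis list had 8 of 13 detected and the immediate early and handling stress list 7 of 15.

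Macrophage transcripts were detected, while polarization markers were almost all under the floor. The general macrophage list had 13 of 19 members detected, including Lyz2, lysozyme (10.02 ± 0.45), C1qa, a complement component (7.46 ± 0.24), Trem2, a myeloid lipid receptor (6.93 ± 0.43) and Csf1r, the receptor for the macrophage growth factor (6.21 ± 0.52, SD, n = 4). With the floor at the 99th percentile of receptor genes, 8 of 19 passed. Csf1r lay close to the floor, from 5.64 in tumour 3 to 6.90 in tumour 1. Of the alternative list, whose genes are induced by IL-4 through STAT6, 1 of 20 was detected. This was Cd209a, a lectin receptor, at 9.82 ± 0.28 (SD, n = 4), read from the brighter of its 2 probe sets. It was highest in tumour 3 (10.13), where most general macrophage genes were lower, so its signal did not follow theirs. Named after their values were seen, Arg1 measured 5.45 ± 0.21, Mrc1 5.85 ± 0.19, Retnla 3.85 ± 0.20 and Chil3 4.56 ± 0.52 (SD, n = 4), all classic markers of alternative activation. Of the classical list, induced by interferon and bacterial products, 0 of 18 were detected, with member means from 3.18 to 5.83. Nos2 measured 5.40 ± 0.23 and Tnf 5.17 ± 0.17 (SD, n = 4), both also named after their values were seen. With the floor lowered to the receptor median, 17 of 20 alternative and 16 of 18 classical members passed it, so these genes lay in the range where signal and background overlap. The low alternative count cannot be tied to the genotype without Stat6-intact tumours.

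**Figure D1:**
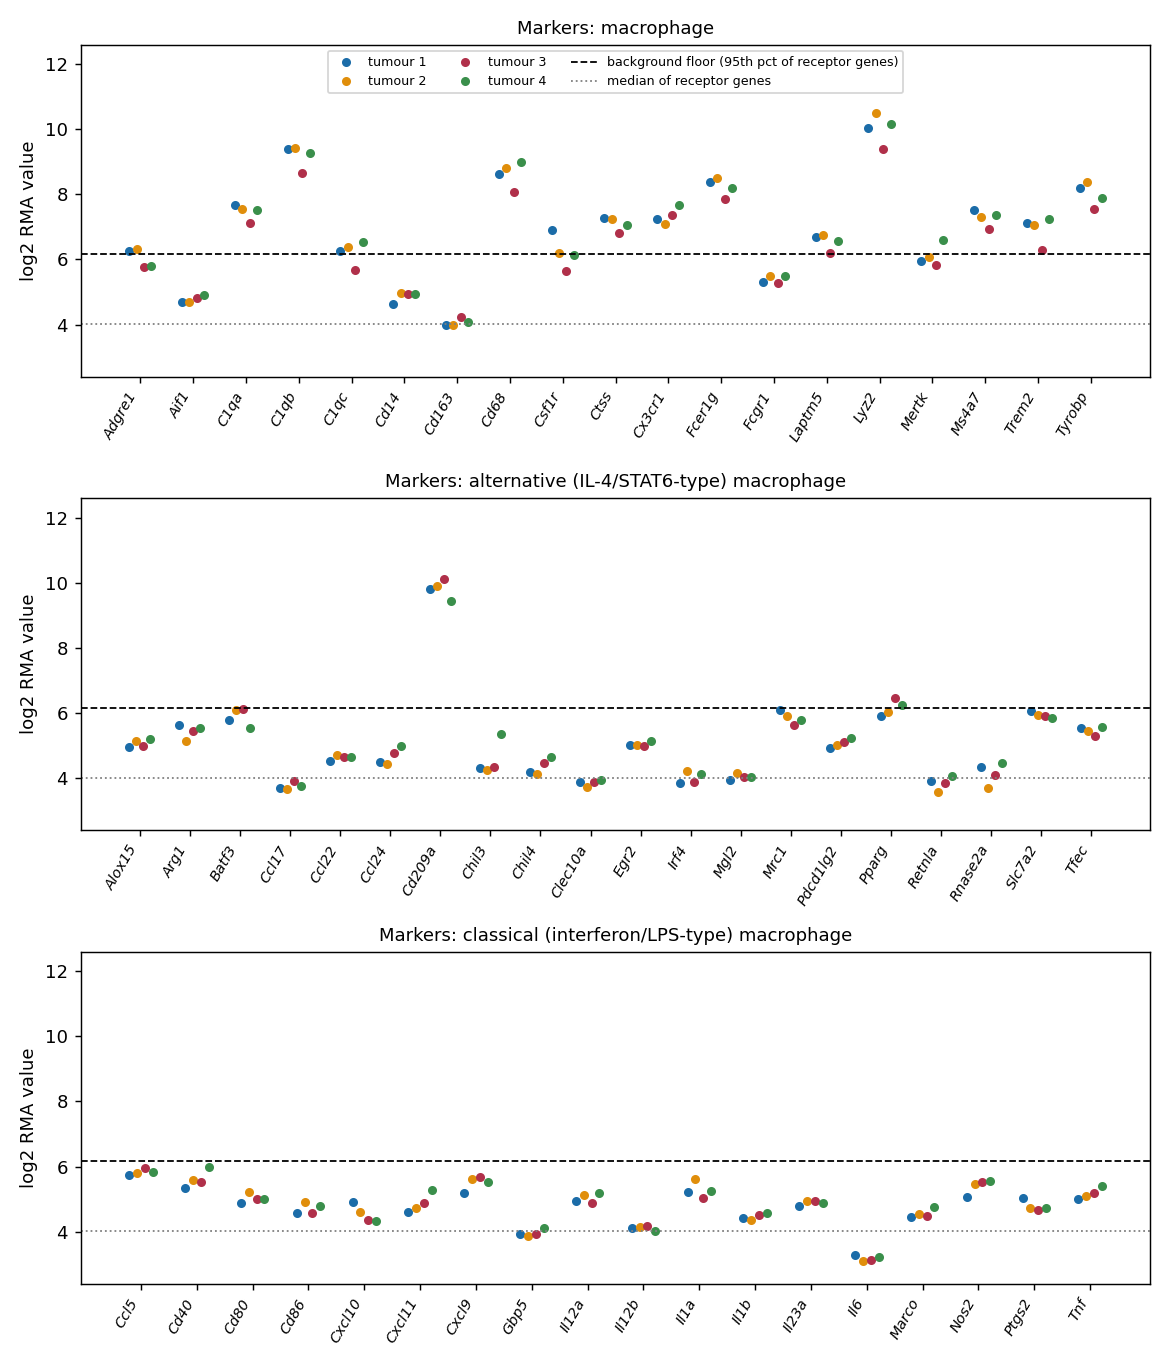
Log2 expression (vertical axis) of each measured marker (horizontal axis) in the general, alternative and classical macrophage lists; each point is 1 tumour, the dashed line is the background floor (6.17) and the dotted line the receptor median (4.01). 13 of 19 general, 1 of 20 alternative and 0 of 18 classical markers have a mean above the floor; heights of different markers are not comparable.

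Markers of other infiltrating or neighbouring cells were mostly under the floor. Detected members numbered 0 of 15 for neutrophils, 0 of 14 for mast cells and eosinophils, 1 of 17 for T and NK cells (Prf1, perforin), 1 of 14 for B and plasma cells (Ighm), 2 of 17 for interferon response (Ifit3 and Stat2) and 4 of 13 for MHC class II and antigen presentation. The endothelial list had 2 of 17, Cdh5 and Egfl7. Fibroblast and extracellular matrix genes had 12 of 19 detected, pericyte and smooth muscle 4 of 13 and Schwann cell genes 3 of 11. The labels name a muscle as the tissue, and 0 of 20 skeletal muscle genes passed the floor, with member means between 3.63 and 5.86. Adrenal cortex had 1 of 11 (Scarb1), adipocyte 2 of 11, erythroid and blood 0 of 5, liver and kidney 0 of 12, and lymph node and thymus stroma 1 of 8. That last gene was Prox1, a transcription factor of lymphatic endothelium and also of neural cells, at 9.10 ± 0.33 (SD, n = 4).

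Over the 4 tumours, most detected genes varied less than 2-fold. The median gene had a range of 0.41 log2 units over the 4 tumours. The range reached 1 in 383 genes (4.26%) and 2 in 37. Without tumour 1 there were 252 such genes with a range of 1, and without tumour 4 there were 227. Pairs differed by at least 2-fold in 50 genes (tumours 1 and 2) to 159 genes (tumours 1 and 4). Pearson's r across detected genes was between 0.946 and 0.977, which mostly reflects differences in level between genes, and genes are not independent replicates. Vip, a neuropeptide of sympathetic neurons, ran from 6.69 in tumour 2 to 9.85 in tumour 3. Gal, galanin, measured 9.56 in tumour 3 and between 7.01 and 7.18 in the others. Fabp7, a glial fatty acid carrier, ran from 6.49 in tumour 3 to 9.54 in tumour 1. Terc, the RNA template of telomerase, spanned 4.47 log2 units, with 11.18 and 11.02 in tumours 1 and 2, 6.71 in tumour 3 and 8.32 in tumour 4. Calcrl, the calcitonin receptor-like receptor, ran from 4.75 to 7.45, Gpm6a, a neuronal membrane glycoprotein, from 5.82 to 8.48, Igf2bp3, an oncofetal RNA-binding protein, from 5.08 to 7.63, Htr2b, a serotonin receptor, from 6.00 to 8.41, Dgkk, a diacylglycerol kinase, from 6.20 to 9.11, S100a10, an annexin partner, from 7.53 to 10.03, and Mid1, a ubiquitin ligase, from 7.98 to 10.54.

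Genes of the Y chromosome set tumour 4 apart. Eif2s3y measured 3.90 in tumour 4 against 7.47 to 7.89 in the others, and Uty 3.89 against 7.24 to 7.58. Srsy, a Y-linked gene of a multicopy family whose probe sets can share signal, was also lowest in tumour 4, at 6.02. Astx5, of a multicopy family on X, was lowest there too, at 7.01. Xist, the RNA of the inactive X chromosome, named after its values were seen, measured 10.13 in tumour 4 and 3.89 to 3.95 in tumours 1 to 3. The labels do not give the animals' sex. By Xist and the Y genes together, tumour 4 reads as female and tumours 1 to 3 as male. Other differences of tumour 4 therefore cannot be told apart from sex. Without genes on X and Y the number of variable genes was 354.

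In 6 lists the mean over members varied more across tumours than in random lists of like expression. These were fibroblast and extracellular matrix, adrenal chromaffin, Schwann cell, macrophage, cell cycle, and MYC targets with ribosome biogenesis. A few widely varying members can raise this spread, so it does not show that the members moved together. The SD over tumours of the list mean was 0.38 for fibroblast genes, 0.44 for chromaffin genes, 0.29 for macrophage genes and 0.26 for cell cycle genes, where random lists gave medians of 0.11, 0.12, 0.10 and 0.12. Over the 16 lists with enough members and 4 tumours, 19 of 64 shifts stood apart, where the percentile limits alone would give 0.64. Genes of 1 cell type are co-expressed, which random lists are not. Without tumour 3 the number of lists with a spread beyond random lists was 2 and the number of shifts standing apart 12.

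Fibroblast and matrix genes were higher in tumour 1 and lower in tumours 2 and 4. The relative shift was 0.36 ± 0.37 (SD over 12 members) in tumour 1, where 11 of 12 members were above genes of like level, -0.27 ± 0.26 in tumour 2 and -0.35 ± 0.33 in tumour 4. Dcn, decorin, measured 8.26 in tumour 1 and 6.17 to 6.55 in the others. Postn, periostin, ran from 7.57 in tumour 4 to 9.44 in tumour 1. Pericyte and smooth muscle genes were also low in tumour 4, -0.29 ± 0.21 with 3 of 4 members lower, at percentile 0.51, just inside the limit. Thy1 behaved otherwise, with its highest value, 7.95, in tumour 3. The call for tumour 2 was lost without tumour 1 (-0.06) and with no floor (-0.08), and its shift was -0.18 without tumour 3 and -0.15 with the floor at the receptor median. The shift in tumour 4 was -0.19 without tumour 1 and -0.18 without tumour 3.

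Macrophage genes were lower in tumour 3, with a relative shift of -0.36 ± 0.18 (SD over 13 members), below every one of 10000 random lists. 12 of the 13 members were lower and 1, Cx3cr1, named after its values were seen, was not. In tumour 4 the list was at 0.17 ± 0.17, with 12 of 13 members higher and percentile 99.3, which did not stand apart. Trem2 measured 6.29 in tumour 3 against 7.07 to 7.24, Lyz2 9.41 against 10.04 to 10.49 and Csf1r 5.64 against 6.13 to 6.90. The antigen presentation list was lower in the same tumour, -0.43 ± 0.32 over 4 members, and higher in tumour 2, 0.35 ± 0.29. In it H2-K1, a class I molecule, ran from 6.45 in tumour 3 to 7.74 in tumour 2, H2-Ab1, a class II chain, was lowest in tumour 3 (6.10) and highest in tumour 1, and B2m, the class I light chain, ran from 9.82 in tumour 3 to 10.98 in tumour 2. In tumour 4 B2m (9.92) and H2-Ab1 (6.27) lay nearly as low as in tumour 3, while H2-K1 (7.02) did not. The list as a whole was at -0.12 ± 0.24 in tumour 4, at percentile 10.7. Tap1, the peptide transporter, was the member that lay higher in tumour 3 (6.62 against a mean of 6.52), and it measured 6.62 in tumour 4 as well. Both antigen presentation calls were lost with the floor at the receptor median, at -0.16 and 0.11, and with no floor, at -0.15 and 0.10, and the shift in tumour 2 was 0.21 without tumour 3. The immediate early and handling stress list was higher in tumour 3, by 0.29 ± 0.23 over 7 members, as were small nucleolar and Cajal body RNAs (0.39 ± 0.23, SD over 61 genes, a class added after seeing the data). These RNAs were lower in tumours 2 and 4, at -0.16 ± 0.28 and -0.22 ± 0.30. The immediate early shift was 0.17 without tumour 2, and with the floor at the 99th percentile, where 3 members remained, it was 0.30 at percentile 99.1 and no longer stood apart.

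Chromaffin genes, neuropeptides and secretory granule genes that tumour cells of this lineage also express, were higher in tumour 3, 0.49 ± 0.69 (SD over 8 members, 7 of them higher), and lower in tumours 1 and 2, at -0.16 ± 0.58 and -0.21 ± 0.63. Tumour 4 lay as low, -0.17 ± 0.58 with 6 of 8 members lower, but at percentile 0.76 did not stand apart. The members did not share 1 order: Gal was high in tumour 3 alone, Vip in tumours 1 and 3, and Npy, neuropeptide Y, was lowest in tumour 4 (7.75 against 9.15 to 9.62). Both lower calls were lost without tumour 3, at -0.06 and -0.05. The call for tumour 1 was also lost without tumour 2 (-0.14) and with means over members (-0.08), and its shift was -0.07 with the floor at the receptor median or no floor. The call for tumour 2 was also lost with the floor at the receptor median (-0.19), with no floor (-0.19) and with unmatched random lists, and its shift was -0.32 without tumour 1 and -0.39 with means over members. The Schwann list rested on 3 members and was lower in tumour 3, -0.49 ± 0.94, and higher in tumour 1, 0.23 ± 0.56, with Fabp7 the most variable. Tumour 4 had the same shift as tumour 1, 0.23 ± 0.26, at percentile 96.2, which did not stand apart. Fabp7 and Gfra3, a neurotrophic factor receptor, were lower in tumour 3 and Pmp22, a myelin protein, was not. The call for tumour 3 was lost with the floor at the receptor median (-0.09) and with no floor (-0.08). That for tumour 1 was lost without tumour 2 (0.22) and with unmatched random lists, and its shift was 0.54 with means over members.

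Cell cycle genes were higher in tumour 2, 0.17 ± 0.16 (SD over 19 members, 17 of them higher), and lower in tumour 4, -0.12 ± 0.12 (17 of 19 lower). In tumour 3 they lay nearly as low, -0.10 ± 0.10 with 17 of 19 lower, though at percentile 0.78 this list did not stand apart. Plk1 measured 10.41 in tumour 2 and 9.41 in tumour 4, and Cdc20, the activator of anaphase, 9.65 and 8.75. MYC target genes followed, with 0.14 ± 0.13 in tumour 2 and -0.12 ± 0.14 in tumour 4 over 19 members. Srm measured 11.13 and 10.14, and Hspd1, a mitochondrial chaperone, 9.83 and 9.01. Both tumour 4 calls were lost after a further quantile normalization, with shifts of -0.11 and -0.12, without tumour 2, with -0.06 and -0.07, and with means over members, both at -0.13. The MYC target call for tumour 4 was also lost without tumour 3 (-0.13), with no floor (-0.12) and with the floor at the 99th percentile (-0.12), and that for tumour 2 without tumour 4 (0.08). The sympathoadrenal list lay the other way, -0.15 ± 0.19 in tumour 2 and 0.24 ± 0.27 in tumour 4 (SD over 27 members), with 24 of 27 members higher in tumour 4. Prph, its widest member, went against this and was lowest in tumour 4 (7.51). In tumour 1, where Prph, Slc6a2 and Slc18a1 were highest, the list was at -0.04 with 19 of 27 members lower and did not stand apart. The call for tumour 2 was lost without tumour 4, at -0.07. The ALK and MYCN axis was lower in tumour 2, -0.35 ± 0.33 over 11 members, among them Dusp6 and Spry4 (6.28 against 6.63 to 7.20), and this shift turned to 0.030 with the floor at the 99th percentile, where 5 members remained. It was -0.19 without tumour 3, -0.19 with the mean of probe sets, -0.15 with the floor at the receptor median and -0.11 with no floor. Hypoxia, oxidative phosphorylation, pericyte, mesenchymal, JAK-STAT6 and strain-variable lists did not stand apart in any tumour. The nearest of these, besides pericyte genes in tumour 4, were hypoxia genes in tumour 3 (0.18 ± 0.37 over 8 members) and oxidative phosphorylation genes in tumour 2 (0.12 ± 0.13 over 13 members). The strain-variable list, genes known to differ between the parental strains, had 3 of 7 detected and its widest member was Glo1, from 6.13 in tumour 3 to 7.12 in tumour 1.

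**Figure D2:**
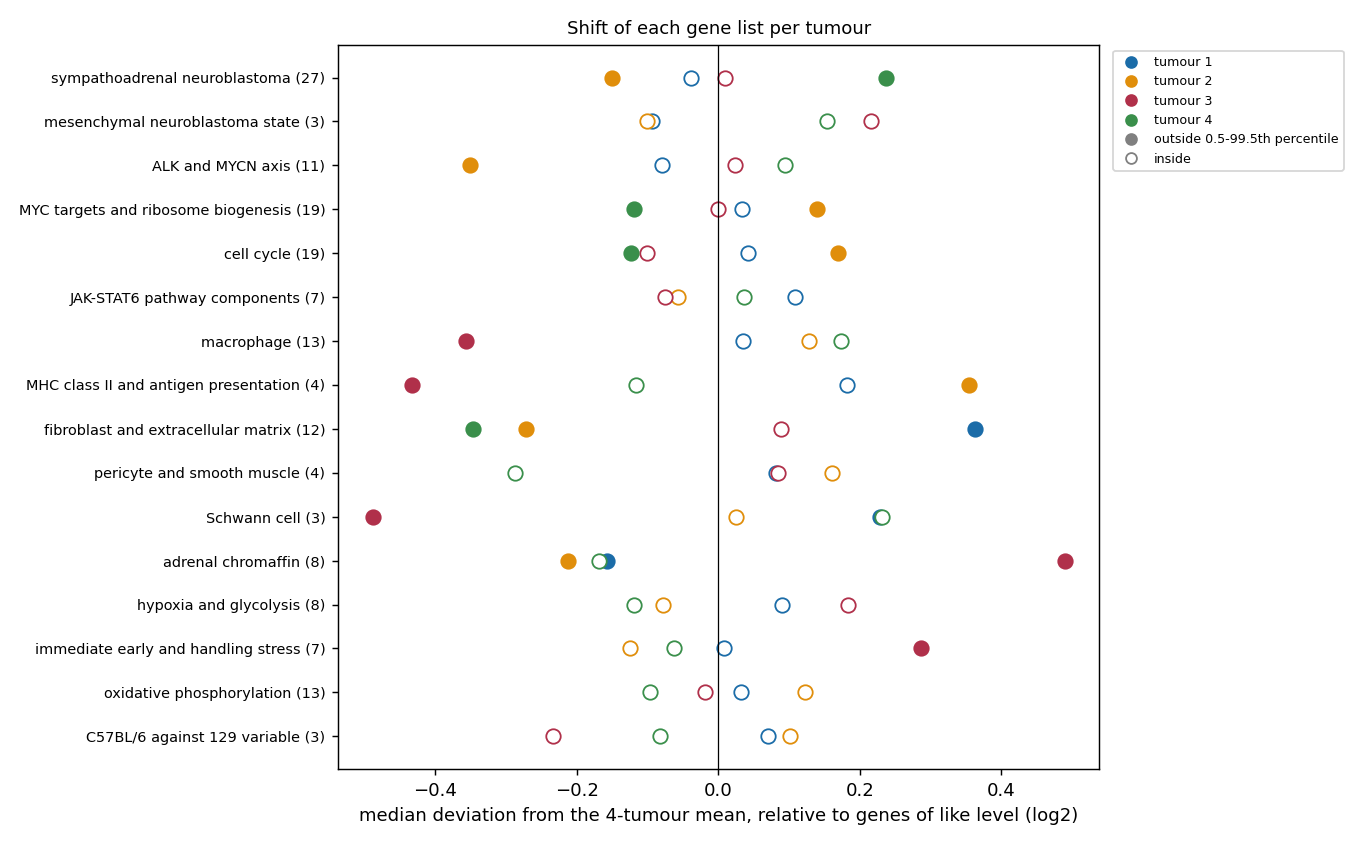
Relative shift of each gene list (rows, with the number of detected members) in each tumour, in log2 units; a point is the median over members, and filled points stand apart from 10000 matched random lists. Macrophage genes sit at -0.36 in tumour 3, and fibroblast genes at 0.36 in tumour 1 and -0.35 in tumour 4.

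Grouped by chromosome, a comparison added after seeing the data, the 435 detected genes of chromosome 3 were higher in tumour 4, by a median of 0.27 ± 0.24 (SD over genes) relative to genes of like level, and 401 of them (92.2%) were above it. In tumours 1 to 3 the chromosome stood at -0.08, -0.08 and -0.11. Tumour 4 differed from the mean of the other tumours on this chromosome by 0.38 log2 units (1.30-fold) more than on the rest of the genome. On the other autosomes and X, the largest shift in size in any tumour was 0.04, on chromosome 13 in tumour 2.

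**Figure D3:**
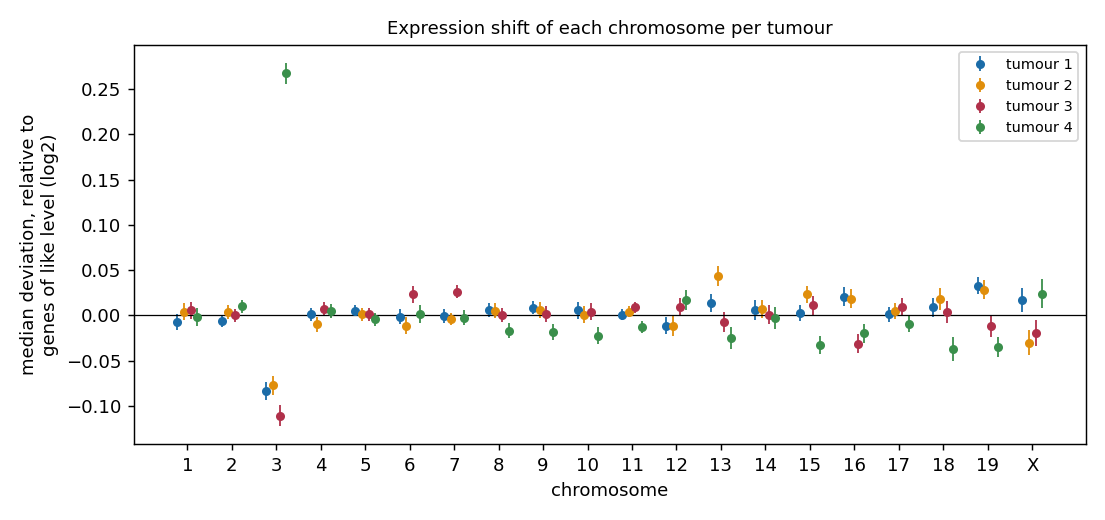
Median relative deviation (vertical axis, log2 units) of the detected genes of each chromosome (horizontal axis) in each tumour; bars are the standard error over genes. Chromosome 3 stands at 0.27 in tumour 4 and between -0.11 and -0.08 in tumours 1 to 3, and the largest shift of any other chromosome is 0.04 in size.

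Among the variable detected genes, those set apart in 1 tumour were no more frequent than normal values without structure would give. Of the 383 variable genes, 14 (3.66%) had a Dixon ratio past the critical value, against 19.3 expected. In tumour 1 these were Sorcs1, a neuronal sorting receptor (8.42 against 6.45 to 6.53), Tmem47, Ifitm2 and Pcdhga10, all higher. In tumour 3 Gal and Rpl3, a ribosomal protein with pseudogene copies (11.10 against 9.44 to 9.52), were higher, and Lix1 and Hecw1 lower. In tumour 4 Eif2s3y, Uty, Gm20816, C1ql1 (6.86 against 8.21 to 8.43) and Grasp were lower. The remaining gene, the microRNA gene Mir680-3, named after its values were seen, was higher in tumour 4, at 7.25. No gene met the criterion in tumour 2. The simulated normal values passed neither the floor nor the range limit, so the observed and expected counts are not strictly comparable. A gene on in 1 tumour only can also miss the floor by its mean, as Xist did (mean 5.47, ratio 0.991). The comparison therefore gives no general statement on such genes.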

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

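The test of array scaling for the macrophage list was stated before its result; the other tests in this part were chosen after the values they measure had been seen. Of simulated groups of 4 normal values, 5.04% passed Dixon's 95% critical value, and many genes were looked at.

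Chromosome 3 genes were set apart in tumour 4, with a ratio of gap to range of 0.912. A further quantile normalization, after which the shift lay at percentile 100 of matched random lists, could not decide on expression level or array scaling. The shift and those lists are already set against genes of like level on the same array, so such effects largely cancel beforehand. A single region, such as a segment of one parental strain, is argued against: in 3 sections of 145 genes each along the chromosome, the lowest shift in tumour 4 was 0.255 and each section lay above all random lists. A gain of the whole chromosome in the cells of tumour 4 is a candidate explanation, since the shift was spread over the sections. With 3 copies in place of 2 in this tumour, the deviation from the 4-tumour mean would be 0.44. The sections lay under this value, at 0.255 to 0.292, as any small rise would, so this adds no support. DNA was not measured, and a gain present in only some of the cells, or array compression, cannot be separated from the size of the shift. That 92.2% of its genes lay higher restates the pattern and adds no support, and whether a gain arose in the tumour or was carried by the animal stays open.

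The macrophage list was set apart in tumour 3, with a ratio of 0.844 for the median deviations fixed beforehand; for the relative shifts the ratio was 0.741, under the critical value. A further quantile normalization, after which the shift was -0.358, could not decide on array scaling. The shift and the random lists are already set against genes of like level on the same array, so such scaling largely cancels beforehand. A smaller share of all non-tumour cells was tested first on the fibroblast list, whose shift of 0.0892 (standard error 0.11 over 12 members) lay too close to the bound of -0.12 to decide. A second test, run only because the first was undecided, took 18 fibroblast, pericyte and endothelial members together and gave 0.138 with a standard error of 0.07, above the bound by more than 2 standard errors; chosen in this way, it does not settle the matter, and the explanation stays open. Fewer macrophages, lower expression per macrophage and differences in sampling or handling stay open: that 7.69% of the members (1 of 13) lay above genes of like level restates the pattern, and no biological explanation from the design was tested, as all tumours have 1 genotype.

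Terc spanned 4.47 log2 units between tumours, a range seen after the data were examined. A lower yield of small structured RNAs on the array of tumour 3 is argued against, because small nucleolar and Cajal body RNA genes had a shift of 0.392 there, opposite to Terc. In tumour 4, where Terc stood at -0.99 from its mean, these genes were low as well, at -0.217. In tumour 2 they were also low, at -0.163, while Terc stood 1.71 above its mean. Low values of this class thus did not go with low Terc in each tumour, and for tumour 4 a lower yield stays open. A copy number change of the whole of chromosome 3, which holds Terc, is argued against for tumour 3. That chromosome's shift there was -0.111, near the -0.083 and -0.077 of tumours 1 and 2, while Terc stood at -2.60 from its mean in tumour 3. These shifts are deviations from a 4-tumour mean that tumour 4 raises. A change confined to the region around Terc was not tested and stays open. A sequence difference between the parental strains under the probes stays open and could not be tested without genotypes.

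Xist, Chil3, Pecam1, Kdm5d and Nos2 were named after their values were seen. Of these, Chil3, Pecam1 and Nos2 lay under the floor in every tumour, where genes are undetermined. The range was under 1 log2 unit for Pecam1 (0.32), Nos2 (0.49), Ccna2 (0.345) and Prox1 (0.70). Xist had a ratio of gap to range of 0.991, Chil3 of 0.917, Uty of 0.908, Eif2s3y of 0.896, Pecam1 of 0.857, Gm20816 of 0.846 and Kdm5d of 0.840, each with tumour 4 apart. Tumour 1 was apart in Sorcs1 (0.958), Ifitm2 (0.903), Pcdhga10 (0.895), Tmem47 (0.872) and Nos2 (0.844). Tumour 3 was apart in Rpl3 (0.949), Gal (0.931), Prox1 (0.906), Lix1 (0.904), Ccna2 (0.877) and Hecw1 (0.841), and tumour 4 in C1ql1 (0.860) and Grasp (0.8295).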

How the results depend on the processing

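The alternatives without X and Y, without chromosome 3 and for the chromosome 3 shift were chosen after seeing the data. With the floor at the 99th percentile of receptor genes there were 5612 detected genes, 206 variable genes, at most 88 genes differing 2-fold in a pair and 6 genes set apart in 1 tumour; at the receptor median these were 19086, 584, 249 and 27, and 423 list members were detected in place of 174. Without a floor 28 genes were set apart. With a range of at least 2 there were 37 variable genes and 4 set apart, and with a difference of at least 2 the widest pair had 17 genes; these follow from the stricter thresholds. Leaving out each tumour in turn gave 227 to 273 variable genes (252 without tumour 1, 227 without tumour 4). These exclusions also gave 8421 to 9164 detected genes, 137 to 158 genes in the widest pair and 167 to 178 detected list members. Between 2 and 6 lists had a spread beyond random lists, and 12 to 21 shifts stood apart. Fewer tumours give a smaller range, and both list counts were lowest without tumour 3. Over the same exclusions Stat6 averaged 5.79 to 5.85, Alk 7.91 to 8.15 and Mycn 6.36 to 6.65. The other counts stayed within 1.5 times the reported value under these settings, under an SD of at least 0.5, median centring, quantile normalization, the mean of probe sets, unmatched random lists, means in place of medians and without the genes of X and Y or of chromosome 3. Of the single list shifts that stood apart, the ALK and MYCN axis in tumour 2 reversed to 0.030 with the floor at the 99th percentile, where fewer genes were tested. Over all alternatives 205 values for single lists and chromosome 3 kept their side of the percentile limits and 29 lost it with the same sign. The cause was not tested. Median centring moves all genes of an array alike, so its values among the 205 were fixed in advance and add no support. The macrophage shift in tumour 3 (-0.39 to -0.26) and the chromosome 3 shift in tumour 4 (0.20 to 0.29) kept their side of the limits in each alternative with a percentile. For chromosome 3 with the mean in place of the median, only the shift, 0.27, is given. No paired analysis was possible because there is 1 group. Signal over background limits what can be said of dim genes, the polarization markers among them.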

Other observations

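The gene classes in this part, and the histone genes named, were chosen after the data were examined; the gene lists and the setting without a floor were not. Histone genes, whose transcripts are made in S phase, were higher in tumour 2 (0.36 ± 0.24, SD over 12 genes, 11 of them higher) and lower in tumours 3 and 4 (-0.19 ± 0.31 and -0.18 ± 0.30), with tumour 2 highest as in the cell cycle list. H2ac10 measured 11.63, 11.90, 11.20 and 11.20 in tumours 1 to 4, while H1f1 was highest in tumour 1, at 7.35, 6.69, 5.40 and 5.34. Many histone genes are near-identical copies, so a probe set can read several. Ribosomal protein genes were higher in tumour 3, 0.10 ± 0.22 (SD over 49 genes, 37 of them higher), and lower in tumour 1, -0.07 ± 0.13 (12 of 49 higher).

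Without a floor, the interferon response list was higher in tumour 1, 0.17 ± 0.23 (SD over 17 members, 13 of them higher, percentile 99.8), and the B and plasma cell list in tumour 3, 0.13 ± 0.12 (14 members, 12 of them higher). Most of these members lay under the floor. The alternative macrophage list showed no shift beyond random lists in any tumour without a floor, with shifts from -0.02 in tumour 1 to 0.03 in tumour 4 over 20 members, and the T and NK cell list was at 0.08 in tumour 4 (13 of 17 members higher, percentile 97.7). Neutrophil genes were at 0.09 in tumour 4 (13 of 15 higher, percentile 98.6) and -0.12 in tumour 1 (2 of 15 higher, percentile 0.72). These T, NK and neutrophil shifts did not stand apart.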
